A study of Homo sapiens with 8 samples.

How the data were processed

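RNA sequencing had been done on 8 clones of RPMI-8402, a cell line of T-cell acute lymphoblastic leukaemia. The labels put 4 clones in an NKX2-1 knockout group (C12, C15, S04 and S36) and 4 in a wild-type group (WT10, WT13, WT28 and WT30). The authors deposited raw counts per gene for these clones in a single table of 61228 gene symbols. Per the labels' protocols, total RNA was extracted with a column kit and made into Illumina libraries. Per the submitters' processing notes, FastQC, TopHat2, SAMtools and Subread were used with the hg38 build. Their roles and versions, the gene annotation, the strand setting, any selection of poly(A) RNA and the kind of edit made in NKX2-1 are not given in the sources used here.

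The deposited counts were used as they stand. Library totals ran from 2730285 counts in C15 to 25423215 in C12. A count of 0 allows up to 3 counts, which is 1.10 CPM (counts scaled to a common library total) in C15 and 0.118 in C12. Such floors, and the intervals given for ratios, cover counting error only. Positions came from GENCODE release 29 on the same build, to which 57038 symbols were matched. Lengths of principal transcripts were those of transcripts that this release marks as principal by APPRIS, with the median taken where a gene has several. Counts of each pair of clones were compared by chi-square per degree of freedom, which was at least 14.1 among wild-type clones and 29.7 among knockout clones, so no library was taken for a copy of another.

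Genes were filtered with filterByExpr, which left 14243, and normalised with TMM factors. Knockout and wild-type clones were compared with the two-sided edgeR quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. C-named and S-named knockout clones were compared in a fit with 3 groups, wild-type clones being the other. The labels do not say what divides C from S clones. Gene lists, 41 in all, were fixed before the data were examined. They were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 40 lists with at least 5 tested members. Beside it an estimated correlation and fry were run. Single values were compared by exact two-sided permutation over 70 assignments of the clones, whose smallest possible p is 0.0286.

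The genes named were NKX2-1 and RUNX1, the 12 genes each way with the largest change among those past the threshold, and up to 4 members of each list by smallest p. Genes named for size needed a mean CPM of at least 1 in the higher group, no overlap between groups, and a symbol that is not a clone, antisense or pseudogene name. The 8 genes named for the C and S contrast, the genes named for lying on chromosome 2 or 9, and MT-RNR1, given as a share of counts, were chosen after their values were seen. So was the choice to name 4 members of lists past the threshold and at most 2 of others. A gene that the rule names is not reported here.

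The gene test was tried on simulated counts with 200 of 14243 genes changed. For the knockout and wild-type comparison edgeR recovered 33.2% of genes planted at 2-fold and 80% at 4-fold, and 5.98% of its calls were false. For DESeq2 1.42.0 these shares were 47.8%, 85.8% and 17.5%. The simulated genes varied independently and with the same dispersion in both groups, unlike those of these clones, so the shares may not carry over. Alternatives covered normalisation, low-count filters, tools, leaving out each clone, and the C or S clones alone. Thinning to the shallowest library, also for the spread between clones, and leaving out mitochondrial and histone genes or the chromosomes that shift, were added after seeing the data. The labels name separate clones but no culture or sequencing dates, so p-values measure the spread between these clones, part of which may be technical. Standard errors of medians over sets of genes or a chromosome came from resampling genes and hold no spread between clones.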

Results

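The data compare 4 NKX2-1 knockout clones with 4 wild-type clones of RPMI-8402, to ask how transcription differs without NKX2-1, a homeobox factor best known from lung and thyroid. The series title names cooperation with RUNX1 and protection from DNA damage. Library totals were 25423215 counts in C12, 2730285 in C15, 15340134 in S04 and 12344549 in S36, and 18453947 to 22916424 in wild-type clones. Mitochondrial transcripts took 21.2% of counts in C15, 18.5% in S04, 16.8% in S36 and 14.8% in C12, against 12.9% to 15.1% in wild-type clones.

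NKX2-1 mRNA was not lower in every knockout clone. Its level was 72.0 CPM in C12, 11.3 in C15, 83.6 in S04 and 33.4 in S36, against 56.9 ± 4.40 CPM (SD, n = 4) in wild-type clones. The log2 fold change was -0.15 (SE 0.42, edgeR adjusted p = 0.905), and an exact permutation test of log2 CPM gave p = 0.543. Its sign turned without C15 (0.14) or without S36 (0.017). NKX2-1 lies on chromosome 14 from 36516392 to 36521149, where its exons overlap SFTA3 on the same strand and NKX2-1-AS1 on the other. Gene-level counts cannot show an edit of the coding sequence, so these values do not check the labels, and the C15 value rests on 28 counts. RUNX1, a core factor of blood development on chromosome 21 from 34787801 to 36004667, was at 298 CPM in S04, 266 in S36, 184 in C12 and 180 in C15, against 196 ± 9.23 CPM in wild-type clones. Its log2 fold change was 0.25 (SE 0.18, edgeR adjusted p = 0.547), with an exact permutation p of 0.429.

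**Figure D1:**
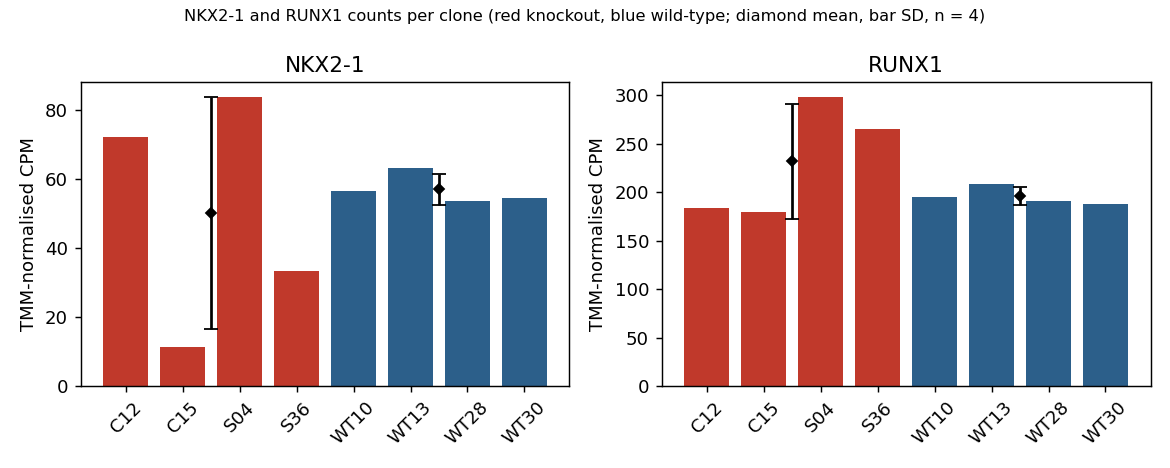
TMM-normalised CPM of NKX2-1 and RUNX1 (vertical axes) in each clone (horizontal axes), knockout clones in red and wild-type clones in blue, with group means as diamonds and SD (n = 4) as bars. NKX2-1 ran from 11.3 CPM in C15 to 83.6 in S04.

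In knockout clones 20 genes rose and 25 fell. NNAT, an imprinted gene for a small membrane protein, rose from 0.206 ± 0.0451 to 19.4 ± 7.87 CPM (SD, n = 4 each), a log2 fold change of 6.52 (SE 0.38, edgeR adjusted p = 3.35e-05). FAM50B, also imprinted, rose from 0.0478 to 3.18 CPM, and SLC16A9, a gene of the monocarboxylate transporter family, from 0.0251 to 1.70. PTPRF, a receptor phosphatase gene, fell from 25.4 ± 11.6 to 2.43 ± 1.41 CPM, a log2 fold change of -3.55 (SE 0.48, edgeR adjusted p = 0.0239). SPEG, a striated muscle kinase gene, fell from 8.79 to 1.59 CPM, and CBX7, a Polycomb subunit gene, from 5.55 to 1.37.

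The wild-type clones together held 2 counts of SLC16A9, 4 of FAM50B and 6 of TACC2, so the size of these changes is loosely known. The ratio of knockout to wild-type was 74.5 for SLC16A9 (95% counting interval 20.1 to 623), 68.5 for FAM50B (26.3 to 254) and 25.1 for TACC2 (11.1 to 69.8). RAB7B (log2 fold change 3.03), PLXDC2 (2.73), CRAT (2.47), CEL (2.16), FAM241A (2.08), MYO1A (1.91), TAC3 (1.87) and USP3 (1.78) also rose. CDR2L (log2 fold change -3.33), ARHGAP19-SLIT1 (-3.12), ADTRP (-2.71), PPM1N (-2.51), GDF10 (-2.13), MIR646HG (-2.08), GNA11 (-2.07), ELAVL4 (-1.96) and PCOLCE (-1.74) also fell. MYO1A and TAC3 overlap on the same strand, and ARHGAP19-SLIT1 is a readthrough of ARHGAP19 and SLIT1, so their reads cannot be assigned with certainty. NNAT lies on chromosome 20 from 37521206 to 37523693, opposite BLCAP, and CRAT, PLXDC2, USP3, SPEG, PPM1N, GNA11, CBX7 and PCOLCE also have genes on the other strand. Use of strand in counting is not stated, so reads of such pairs cannot be told apart.

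**Figure D2:**
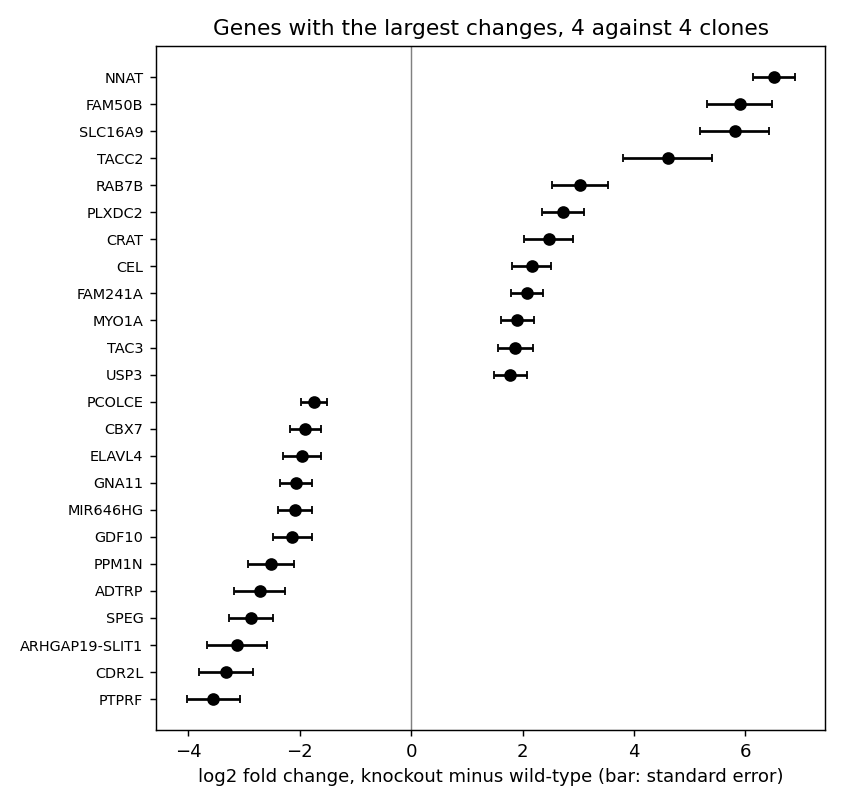
Log2 fold change, knockout minus wild-type (horizontal axis, bars standard error), of the 24 genes with the largest changes past the threshold (vertical axis). Values run from -3.55 for PTPRF to 6.52 for NNAT.

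In all 45 genes every knockout clone lay on one side of every wild-type clone, as in 1432 of the 14243 genes tested, a share of 10.1% against 2.86% by chance. The count of genes past the threshold was 3 without WT10, without WT13 or without WT30, 5 without WT28 and 7 without S04. It was 20 without S36, 114 without C15 and 456 without C12. The 45 genes kept their direction in each of these fits, which the lack of overlap between groups made all but certain. DESeq2 called 521 genes, limma-voom 94, the S clones alone 2211 and the C clones alone 6.

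Several of these genes shared a chromosome. Of the 25 genes that fell, 7 lie on chromosome 2, which is 28% against 6.66% of tested genes (Fisher's exact p = 9.41e-04). They are SPEG, ATP5MC3, AFF3, FEZ2, HNRNPLL, SERTAD2 and SP110. On chromosome 9 SMARCA2, CRAT and CEL rose and no gene fell (Fisher's exact p = 0.0334 for higher genes). On chromosome 10, shifted past 0.25 in S36 alone (0.30), 3 genes rose and 2 fell (Fisher's exact p = 0.0363 for higher genes). Adjusted over the 10 tests of 5 chromosomes in both directions, p was 0.00941 for lower genes on chromosome 2 and 0.121 for higher genes on chromosomes 9 and 10. These 5 of 23 chromosomes were tested because they had shifted in a knockout clone in the same data. Extra calls in the direction of a shift are therefore built in, and genes that share a shift are not independent. The tests thus restate the shift and are no separate evidence. The median log2 difference of chromosome 2 genes from the wild-type mean was -0.37 in C12, C15 and S04 and -0.24 in S36. For chromosome 9 it was 0.20 in C12, 0.45 in C15, 0.41 in S04 and 0.37 in S36, while the largest size in a wild-type clone was 0.043 on chromosome 2 and 0.016 on chromosome 9. Without genes of the chromosomes that shifted in any knockout clone, 28 of the 45 genes were still tested and 27 passed. Parts of chromosomes 8 and 14 that were low in S36 stayed in that fit, such as 60 to 80 Mb of chromosome 8 (-0.41).

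**Figure D3:**
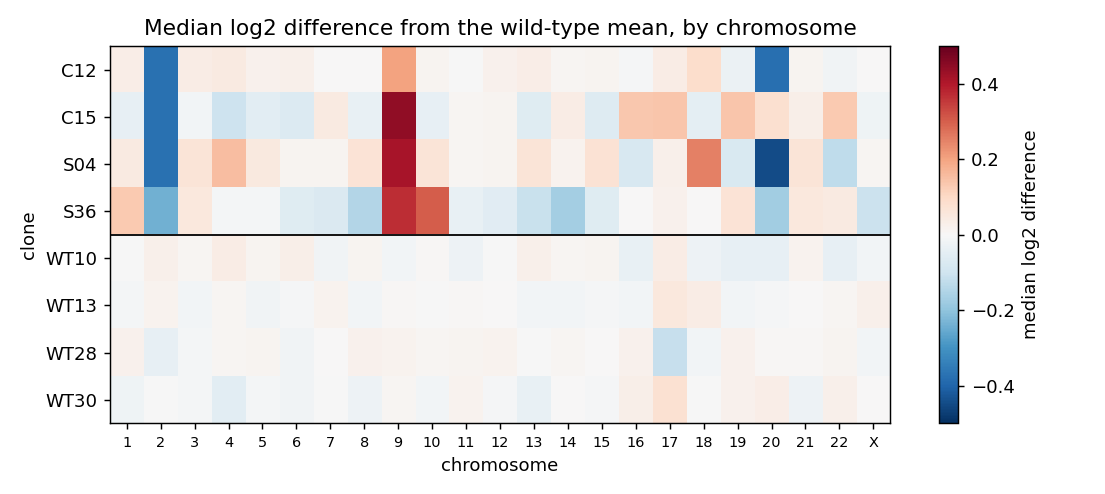
Median log2 difference from the wild-type mean (colour) over genes with a mean CPM of at least 10 on each chromosome (horizontal axis), in each clone (vertical axis). Chromosome 2 is low and chromosome 9 high in the 4 knockout clones, and the largest difference in a wild-type clone is 0.11.

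Among the gene lists, replication-dependent histone genes rose, with a median log2 fold change of 1.68 over 27 tested genes, 0 past the threshold over all genes and 19 higher adjusted over the list alone. Cytosolic ribosomal protein genes fell (median -0.30 over 74 genes, 3 lower adjusted over the list alone), as did nuclear-encoded oxidative phosphorylation genes (-0.24 over 48 genes, 1 lower) and T-cell receptor complex and signalling genes (-0.25 over 30 genes, 4 lower). Homologous recombination and Fanconi anaemia genes, which repair broken and cross-linked DNA, rose (median 0.15 over 53 genes, 2 higher adjusted over the list alone). The camera adjusted p of these lists, in this order, were 1.98e-08, 4.42e-08, 1.37e-04, 0.00641 and 0.0434. With an estimated correlation the unadjusted p were 0.126, 0.0700, 0.0801, 0.0786 and 0.130, and 0 lists passed by camera, with 0 at an unadjusted p under 0.05. By fry 0 lists passed in 1 direction, with 5 at an unadjusted p under 0.05. For change in either direction 5 lists passed by fry, of which ribosomal proteins (adjusted p = 0.0493) and T-cell receptor genes (0.0171) also passed by camera. The others were interferon-stimulated genes (5.23e-05), T-lineage transcription factors (0.0171) and fibroblast and epithelial markers (0.0346), while histone (0.0943), oxidative phosphorylation (0.0617) and repair genes (0.0558) did not pass. The repair list lost its call without C15 (adjusted p = 0.0632), S04 (0.116), S36 (0.10), WT13 (0.0696), WT28 (0.110) or WT30 (0.0759), with no low-count filter (0.0851) and in thinned libraries (0.0558), and the T-cell receptor list without C15 (0.0632). With C clones only the histone and oxidative phosphorylation lists (camera adjusted p = 0.0698 for each) and the repair list (0.473) lost their call, and with S clones only the T-cell receptor list did (0.0888).

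The histone median lay at -0.05 in C12, 0.75 in C15, 1.99 in S04 and 2.19 in S36, and small non-coding RNA genes, which also lack poly(A) tails, had medians of 0.0044, 0.75, 0.77 and 0.99 in these clones. That set was chosen after the data were seen. The list of nuclear and small non-coding RNAs fixed beforehand, which also holds spliced host transcripts, did not pass (median log2 fold change 0.21, 10 genes above 0 and 7 below, camera adjusted p = 0.919) and lay at 0.092, 0.14, 0.28 and -0.17 in these clones. H2BC5 (log2 fold change 1.75), H2AC14 (1.69), H2AC17 (2.29) and H2BC14 (2.42) had the smallest p, and near-identical histone copies make single genes uncertain. The histone genes together took 0.37% of counts in C12, 0.55% in C15, 0.63% in S04 and 0.76% in S36, against 0.33% to 0.45% in wild-type clones. Their summed counts thus rose by less than the median over genes. The ribosomal protein median lay at -0.16 in C12, -0.20 in C15, -0.52 in S04 and -0.62 in S36, against -0.11 in the lowest wild-type clone. The mitochondrial ribosomal RNA MT-RNR1 took 4.51% of counts in S04 and 5.52% in S36, 1.66% in C12 and 2.38% in C15, against at most 2.02% in a wild-type clone, so its share was highest in the clones where the histone, ribosomal protein and oxidative phosphorylation medians lay farthest from wild type. The oxidative phosphorylation median was -0.27 in C15, -0.37 in S04 and -0.58 in S36, but at -0.038 in C12 it lay within the wild-type range, whose lowest value was -0.075. The T-cell receptor median was -0.59 in C15 and -0.37 in S36, but at -0.062 in C12 and -0.11 in S04 it lay within the wild-type range, whose lowest value was -0.14. The repair median was 0.072 in C12, 0.073 in C15, 0.31 in S04 and 0.24 in S36, against 0.053 in the highest wild-type clone. Among ribosomal proteins RPS21 was at -0.82, RPL31 at -0.99, RPL14 at -0.78 and RPL13A at -0.68, genes that have many processed copies in the genome. Among respiratory genes ATP5MC3, a subunit of ATP synthase, fell (-1.25, SE 0.19, edgeR adjusted p = 0.0369), and COX5B was at -0.88, UQCRFS1 at -0.62 and NDUFA10 at -0.48. Among T-cell genes CD6, a surface receptor gene, fell (-0.91, SE 0.15, edgeR adjusted p = 0.0383), and CD28 was at -1.31, CD7 at -1.19 and CD5 at -0.76. Among repair genes FANCG was at 0.78, MCM9 at 0.65, POLQ at 0.63 and FANCC at 0.58. Of these 20 members 7 lie on chromosomes 2 and 9, all with the sign of the shift, and without the shifted chromosomes the repair list had an adjusted p of 0.0781.

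**Figure D4:**
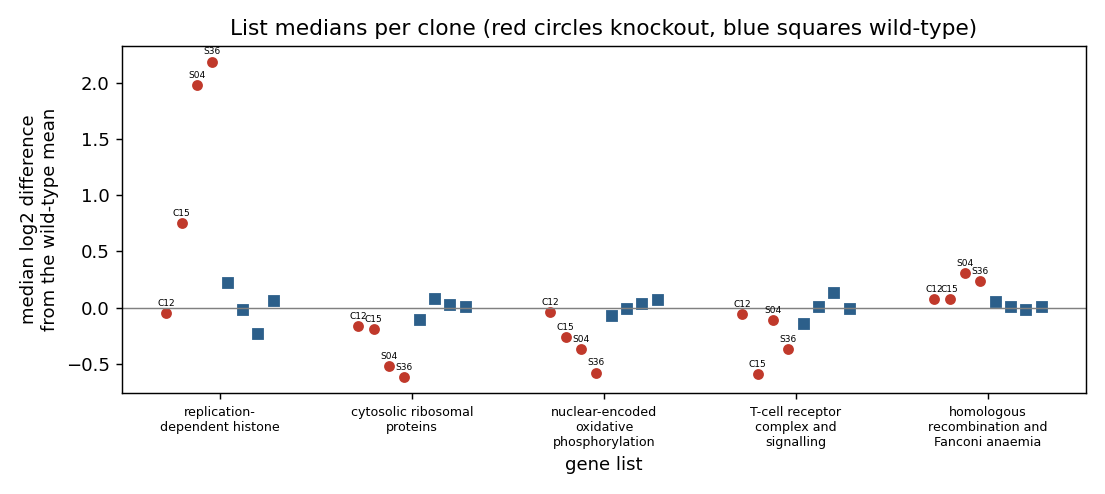
Median log2 difference from the wild-type mean (vertical axis) of the 5 lists past the threshold (horizontal axis) in each clone, knockout clones as red circles and wild-type clones as blue squares. Histone genes ran from -0.05 in C12 to 2.19 in S36.

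Other lists tied to DNA damage did not pass. The camera adjusted p was 0.603 for checkpoint genes (median log2 fold change 0.054), 0.919 for p53 targets (0.076), 0.919 for non-homologous end joining genes (0.086) and 0.982 for excision and mismatch repair genes (-0.028). PLK2, a p53 target, was at 1.52, and XRCC5, which encodes Ku80 and lies on chromosome 2, at -0.56, both past the threshold adjusted over the list alone and not over all genes. DNA replication genes (0.025, adjusted p = 0.919), mitosis genes (0.024, 0.982), nucleotide pool genes (0.080, 0.982) and apoptosis genes (-0.0050, 0.919) did not pass.

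Other lists tied to NKX2-1, RUNX1 and the T-cell lineage did not pass by camera. RUNX factors and partners had a median log2 fold change of -0.076 (camera adjusted p = 0.982), with CBFA2T3 at -2.92 and TLE1 at 0.97, each past the threshold adjusted over the list alone. Of the lung and thyroid genes of NKX2-1 5 were tested (median -0.18, adjusted p = 0.801), with LPCAT1 at 1.30. The NKX2-1 locus list had a median of -0.0094 (adjusted p = 0.919), leukaemia transcription factor oncogenes -0.11 (0.479), T-lineage transcription factors -0.056 (0.792), cortical thymocyte genes -0.25 (0.135), NOTCH1 targets -0.12 (0.903), TAL1 complex targets -0.058 (0.837), early progenitor genes 0.0048 (0.963) and chromatin regulators 0.029 (0.919). Cortical thymocyte genes passed without C12 (camera adjusted p = 0.0337) and with S clones only (0.0327), and the leukaemia oncogenes with C clones only (0.0294).

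What the letters C and S in the names of the knockout clones stand for is not given in the labels, so a difference between them cannot be tied to a guide, a sort or a batch. Between C-named and S-named knockout clones 51 genes differed, 32 higher in C clones and 19 higher in S clones. PRDM16, a zinc finger factor gene, was at 8.09 CPM in C clones and 0.25 in S clones (log2 difference 4.93, SE 0.58, edgeR adjusted p = 0.0311), both below the wild-type mean of 39.8 CPM. FAM83A (3.44), BAIAP2-DT (2.48) and AEBP1 (2.12) were also higher in C clones. The small nucleolar RNA genes SNORD8 (-3.99) and SNORA32 (-3.37), the histone gene H2AC12 (-3.51) and ERV3-1 (-3.52) were higher in S clones. SNORD8 lies within CHD8, SNORA32 within TAF1D, and ERV3-1 overlaps ZNF117, so their reads are uncertain. Each letter has 2 clones. The count was 0 by edgeR without WT10, without WT13, without WT28 or without WT30, with 2027, 2055, 2095 and 1971 genes at an unadjusted p under 0.05, and with all clones DESeq2 called 651 and limma-voom 89. It was 749 without C12, 32 without C15, 148 without S04 and 198 without S36.

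Knockout clones lay farther from each other than wild-type clones did, at a mean root mean square distance of 1.04 in log2 CPM against 0.46. The difference of 0.58 had an exact two-sided permutation p of 0.0571, and without C12 it was 0.68 with p = 0.0286 by the same exact test. Without C15 the difference was 0.39 (exact permutation p = 0.114), and the p ran from 0.0286 to 0.114 over the clones left out. With all libraries thinned to 2730285 counts the distances were 0.77 and 0.40, a difference of 0.37 (exact permutation p = 0.0571).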

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

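The tests of RNA without poly(A) tails, of S phase, of the C12 label and of the C12 chromosome medians were chosen only after the results they bear on were seen.

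In 154 groups of 4 clones, 7 held a clone far from the other 3, where chance gives about 7.7. On the log2 CPM scale these were TACC2 in WT30 (-3.13), SPEG in C15 (1.91), MIR646HG in S04 (2.12), UQCRFS1 in WT28 (6.62), COX5B in C15 (3.79), LPCAT1 in WT28 (-1.51) and TLE1 in S04 (5.04).

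C and S clones differed, by a test of the difference itself, in PRDM16 (log2 difference 4.93), FAM83A (3.44), BAIAP2-DT (2.48), AEBP1 (2.12), SNORD8 (-3.99), ERV3-1 (-3.52), H2AC12 (-3.51) and SNORA32 (-3.37). Among lists they differed in histone genes (median -1.52, camera adjusted p = 1.80e-11), ribosomal proteins (0.27, 1.49e-04), mitochondrially encoded genes (0.69, 0.0164) and MYC targets with ribosome biogenesis genes (0.30, 8.10e-04). With an estimated correlation the unadjusted p were 0.0132, 0.0315, 0.299 and 0.168, and none of these lists passed after adjustment.

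Histone genes were higher in C15, S04 and S36 and not in C12. A much larger share of cells in S phase is argued against by DNA replication genes, whose median log2 fold change was 0.025 (SE over genes 0.064). Against the wild-type mean their median lay at 0.11 in C15, -0.069 in S04 and 0.00068 in S36. A rise of that share too small to move the median of this list is not excluded. More RNA without poly(A) tails in these libraries is a candidate explanation, since 112 tested small non-coding RNA genes, a set chosen after the data were seen, had a median of 0.74 (SE 0.12). The list of nuclear and small non-coding RNAs fixed beforehand, which mixes RNAs with and without such tails, does not add to it, at a median of 0.21 (camera adjusted p = 0.919) and -0.17 in S36, where histone genes were highest (2.19). Whether a higher level of such RNA came from library making or from the cells stays open, and an effect of the knockout was not tested apart from it.

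C12 lay nearest to the wild-type mean, at 0.47 against 0.82 in S04, 0.88 in S36 and 1.14 in C15, the shallowest library. Wild-type clones lay at 0.34 to 0.41 from the mean of the other wild-type clones. The log2 CPM of C12 correlated more with every wild-type clone (Pearson 0.977 to 0.981) than with any knockout clone (0.923 to 0.963). Lower depth of the other knockout libraries is argued against by libraries all thinned to 2730285 counts. There C12 was still nearer than S04 and S36 by 0.27 (SD 0.0039 over 20 draws), at 0.40 against 0.67 in S04, 0.71 in S36 and 0.72 in C15. That C12 is a clone of the same kind as the 4 wild-type clones is argued against by chromosome 2. The C12 median log2 difference there was -0.37 (SE over genes 0.011), and the largest size in a wild-type clone was 0.043. That C12 may be an unedited clone with the descent of the other knockout clones stays open, since the counts do not show the edit and a first test was void, with 0 genes called in any of 6 ways to part the wild-type clones. Over the 200 genes with the smallest p C12 showed a median share of the shift of 0.16 to 0.28 over these ways, neither under 0.1 in each nor above 0.25 in each, while a held-out wild-type clone showed at most 0.093.

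NNAT and FAM50B are imprinted and were higher in all 4 knockout clones. A common rise of imprinted genes through release of silenced alleles is argued against by the other 34 tested imprinted genes. Their median log2 fold change was -0.017 (SE over genes 0.070), with 14 above 0 and 20 below. A median cannot exclude release at single genes, or release that raises some genes and lowers others. The real grouping parted 11 genes by 8-fold or more with no overlap, and the highest of the other splits parted 4. The real count was reached by 1 of 35 splits, the fewest possible, and the other splits mix knockout and wild-type clones. Chance is thus not excluded for that count. An effect of NKX2-1 and descent from another founder cell stay open, and neither was tested.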

How the results depend on the processing

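Thinned libraries, and fits without mitochondrial or histone genes or without the shifted chromosomes, were chosen only after seeing the data. The 24 genes named by size kept their direction in all 504 comparisons with an alternative and passed in 323. Their choice required no overlap between groups, so their direction could hardly have changed. The count of 45 genes became 581 with no low-count filter, 521 with DESeq2, 94 with limma-voom, 29 with library size only and 3 against a 1.5-fold change. It was 6 with C clones only, 2211 with S clones only, 11 thinned and 3 to 456 leaving out 1 clone. Without the shifted chromosomes it was 27, where only 28 of the 45 genes were still tested. Lists went from 5 to 0 by camera with an estimated correlation (0 at an unadjusted p under 0.05) and to 0 by fry (5 at an unadjusted p under 0.05). With other filters, depths, genes or clones the histone, oxidative phosphorylation, T-cell receptor and repair lists each lost their call at least once. Leaving out clones, the cortical thymocyte, leukaemia oncogene, MYC target, glycolysis, mitochondrially encoded and fibroblast and epithelial lists each gained one. The 51 genes between C and S clones became 14 with DESeq2 size factors, 14 with a CPM of at least 1 in 4 clones, 762 with no filter, 651 with DESeq2, 89 with limma-voom and 0 to 749 leaving out 1 clone, where a lone clone of a letter was assumed to vary like the others. The NKX2-1 log2 fold change was -0.48 to 0.14 leaving out 1 clone and 0.031 with S clones only. The difference in spread was 0.39 to 0.68 leaving out 1 clone and 0.37 thinned. The gene values that follow are log2 fold changes of knockout minus wild-type, not the differences between C and S clones given above. With C clones only RUNX1 was at -0.12, FAM83A at 0.64, AEBP1 at 0.67 and SNORD8 at -0.23. In the same fit ERV3-1 was at -1.68, H2AC12 at -0.15 and SNORA32 at -0.34. Each of these signs was opposite to that of knockout minus wild-type with all clones. ERV3-1 was at -0.25 with sample weights and AEBP1 at 0.0090 thinned. Leaving out 1 clone, the FAM83A log2 fold change ran from -1.73 to 0.056 and the AEBP1 log2 fold change from -0.45 to 0.22. Fewer clones or genes entered some of these fits, and otherwise the cause was not tested. Depth limits C15 most, where 3 counts are 1.10 CPM. No paired analysis was possible because the replicate numbers follow accession order and pair no clones.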

Other observations

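The tests of genes against the shift of their chromosome and of lists matched on the length of principal transcripts were chosen only after the results were seen.

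Interferon-stimulated genes went both ways, with GBP1 higher (log2 fold change 1.68, edgeR adjusted p = 0.0369) and SP110 lower (-0.85, 0.0421), and 5 genes higher and 5 lower adjusted over the list alone. The list's fry adjusted p for change in either direction was 5.23e-05, and its camera adjusted p was 0.837. THY1, a surface glycoprotein gene in the fibroblast and epithelial marker list (camera adjusted p = 0.217, and 0.0450 without S04), fell (-1.40, edgeR adjusted p = 0.0421). Markers of B cells (0.665), of natural killer and cytotoxic cells (0.926) and of erythroid cells and megakaryocytes (0.939) did not pass, and of the myeloid markers 2 were expressed, too few for a test.

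Median log2 fold change and camera adjusted p of the remaining lists were 0.22 and 0.479 for mitochondrially encoded genes, -0.15 and 0.479 for MYC targets with ribosome biogenesis genes, 0.14 and 0.479 for cholesterol synthesis genes and -0.20 and 0.479 for glycolysis and hypoxia genes. They were 0.21 and 0.837 for cytokine receptor genes, 0.041 and 0.982 for trafficking and adhesion genes, 0.28 and 0.982 for antigen presentation genes and 0.11 and 0.922 for NF-kB targets. They were 0.0086 and 0.919 for antioxidant genes, 0.0097 and 0.919 for immediate early genes, 0.010 and 0.919 for unfolded protein response genes and 0.21 and 0.919 for nuclear and small non-coding RNAs. Some of these lists passed with fewer clones. Mitochondrially encoded genes did so without S36 (camera adjusted p = 0.0256) and with C clones only (0.00955), MYC targets with ribosome biogenesis genes without C15 (0.0289) and with S clones only (0.00938), and glycolysis and hypoxia genes without S04 (0.00640). The mean, median or test differed in sign for RUNX partners, p53 targets, end joining, excision and mismatch repair, nucleotide pool, T-lineage factor, early progenitor, interferon, antioxidant, immediate early, unfolded protein, NF-kB and erythroid lists.

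The real grouping called 45 genes, the highest of the other splits called 0, and 1 of 35 splits reached the real count. That is the fewest that 35 splits allow, and the other splits mix knockout and wild-type clones, which widens the spread within each side. The real count thus stands apart from those of the other splits, but chance is not excluded for it. For lists 9 of 35 splits reached the real count of 5, with 7 the highest of the others, so chance cannot be excluded.

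Gain or loss of whole chromosomes or large parts is a candidate explanation for chromosome-wide shifts in single clones. Past both bounds were 10 pairs of a knockout clone and a chromosome, and 0 pairs of a wild-type clone and a chromosome lay beyond 0.25. Besides chromosomes 2 and 9 these were chromosome 20 in C12 (-0.38) and S04 (-0.45), chromosome 10 in S36 (0.30) and chromosome 18 in S04 (0.25). On chromosome 2 the 20 Mb parts of S36 lay at -0.17 to 0.020 up to 100 Mb and at -0.25 to -0.58 beyond. Up to 100 Mb those of C12, C15 and S04 lay at -0.24 to -0.75. The part of chromosome 14 from 20 to 40 Mb, which holds NKX2-1, was at -0.47 in S36. Over the whole chromosome, S36 on chromosome 2 and C12 on chromosome 9 shifted the same way as the other knockout clones but short of 0.25. For S36 this was a shift of a part of chromosome 2, not a weaker shift of the whole. Knockout clones may share a founder cell, which was not tested, but 1 inherited shift would not by itself give the different extent in S36. Differences were taken from the wild-type mean, so a change in the wild-type clones would look the same. RNA counts do not measure DNA copies.

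The 10 genes past the threshold on chromosomes 2 and 9 had the sign of the shift of their chromosome, and the size of their fold changes exceeded it by a median of 0.83 (SE 0.30). The smallest size among all genes past the threshold was 0.85, above both shifts, so this excess follows from the choice of genes. FEZ2, HNRNPLL and SERTAD2 lie in parts of chromosome 2 where S36 was at -0.021 (20 to 40 Mb) and 0.020 (60 to 80 Mb). They were still lower in S36 than in every wild-type clone, so there their fall came without a shift of the region. That covers a single clone and genes chosen for their fall, so whether the 10 genes follow the shift stays open.

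Poorer recovery of short transcripts was weighed for ribosomal protein and oxidative phosphorylation genes. In a first test both medians lay at percentile 0 of 10000 random lists matched on length and expression, but its lengths merged all exons of a gene (medians of 3120 and 3151 bases), so it was void for transcript length. With the lengths of principal transcripts (medians of 938 and 1039 bases) oxidative phosphorylation genes lay at percentile 0.01, which argues against length as the whole cause. Members of the random lists were drawn independently, while those of this list are correlated (estimated at 0.12), so the percentile overstates the evidence. Ribosomal protein genes lay at percentile 0, but the matched genes had a mean of 8.24 log2 CPM against 9.22, so for them the explanation stays open.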
